A study of Mus musculus with 7 samples.

How the data were processed

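Gene expression was measured by RNA sequencing of mouse neural stem cells at passage 1, in 3 WT, 2 TFoCa and 2 TMut libraries, each from a separate line according to the design text. The design text writes Tet-FoCa where the sample labels write Tet-TFoCa; the labels are used here. Per the submitters' processing notes, the authors used Trim Galore 0.6.5, STAR 2.7.3a, featureCounts, SAMtools and DESeq2 with genome build mm39; the notes give no settings, and the annotation is not stated. The deposited table holds normalized counts (signal), which are gene counts divided by the DESeq2 size factor of the library.

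Whole reads were recovered from each column within a tolerance of 0.001 read, for 100% of values, and size factors recomputed from them equalled those in the values. Genes with few reads are not in the table, where the smallest sum over the 7 libraries is 71 reads. Reads counted in genes ranged from 33340167 to 62545457 per library, more than the design text states. Of counts from 1 to 20 reads, 70.29% to 79.32% were even, as would arise if both mates of a pair were counted. The floor used for a group at 0 is 3 reads over the group, so leaving out a library of that group weakens the limit by construction. It covers counting error of independent reads only; if both mates were counted, 3 pairs would be 6 reads, and each limit would be weaker by 1 log2 unit. The reference at hand is of another genome build, so no positions are given; it served for gene names, transcript length, GC content and chromosome, and held 97.41% of the symbols.

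Genes with a normalized count of 10 or more in at least 2 libraries were tested, which kept 18134 of 18145. Log2 values with a pseudocount of 1 were fitted by limma 3.58.1 with an intensity trend in R 4.3.3, in 1 model over the 3 genotypes with 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over 39 lists and 3 comparisons (117 tests adjusted together), and again with the correlation estimated from the data. With the estimated correlation 0 lists were called in each comparison, where 2, 2 and 4 had an unadjusted p under 0.05; fry, which tests whether the genes of a list move on balance 1 way, called 12, 23 and 22. The overlap of both mutant genotypes was set against 100 simulations without effect that share the WT libraries. edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads served as alternatives. If both mates were counted, these count models may overstate precision, so genes called by them alone are not taken as called.

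On simulated data with known changes, the test recovered 66%, 71% and 55% of genes changed by 1 log2 unit in TFoCa versus WT, TMut versus WT and TMut versus TFoCa, and 98%, 95% and 95% of those changed by 2. False calls numbered 7, 13 and 9. With the preset correlation, the 1 list given a shift was called in each comparison, as were 0, 1 and 1 other lists, each with 2 changed members. Genes were simulated independently, so correlation was not tested. No comparison has 3 libraries on both sides, so other splits of the libraries were not counted. Replicate numbers were not taken to pair libraries, since deviations from the group means correlated across genes by 0.0192 to 0.185 between libraries of the same number.

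The comparisons, gene lists, naming rule and alternatives were set before the data were examined. The rule takes Tet1, Tet2, Tet3 and Tdg, the sex-linked genes, and the 10 genes with the largest rise and the 10 with the largest fall whose libraries do not overlap between groups and whose mean is 100 or more in the higher group. It also takes the 4 members of each described list with the smallest adjusted p, and 5 genes per direction of the overlap. This gives more genes than a text can hold, so the text names the first 2 of each list and the first 3 of each other part, except that 1 gene is named for the GABAergic list in TMut versus TFoCa. That reduction was chosen after the values were seen. Earlier choices of examples, made by hand after the effect of leaving out a library had been seen, left out genes whose calls were lost in that way. They were discarded: on the last of them 16 of 178 called genes lost their call when some library was left out, against 96 of 465 over every called gene the rule takes, and only the latter count is used. Genes outside the rule are marked as named after their values were seen.

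The alternatives were other pseudocounts, filters, normalizations, tests and thresholds, a fit to 2 genotypes, a replicate block, an estimated correlation, fry, and leaving out each library. Thinning of all libraries to the smallest total was added after the data were seen. Paralogs with near-identical sequence cannot be separated in a table of gene counts, which bears on Zscan4c, Rpl10l and Ifi203.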

Results

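RNA was sequenced from mouse neural stem cells at passage 1. The 7 libraries each came from a separate line, according to the design text: 3 wild-type (WT) lines, 2 lines labelled Tet-TFoCa (TFoCa) and 2 lines labelled Tet-TMut (TMut). The series title sets DNA hydroxymethylation against DNA formylation and carboxylation in these cells. TET enzymes oxidise 5-methylcytosine in steps to hydroxymethyl-, formyl- and carboxylcytosine, and the labels do not say which step each mutant genotype affects. Reads counted in genes came to 50495614, 62545457 and 34610944 in WT replicates 1, 2 and 3. The totals were 41306668 and 33340167 in TFoCa replicates 1 and 2, and 36351320 and 35632516 in TMut replicates 1 and 2. The table lists 18145 genes, of which 18134 were tested. Fold changes below are log2 values with their standard error, from limma over all 7 libraries (n = 3 WT, 2 TFoCa and 2 TMut), and adjusted p values are Benjamini-Hochberg values.

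The first principal component held 55.19% of the variance and set both TMut libraries (scores 87.7 and 134.4) apart from the WT and TFoCa libraries (scores from -53.7 to -37.1). The second held 22.57% and set TFoCa apart from WT.

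**Figure D1:**
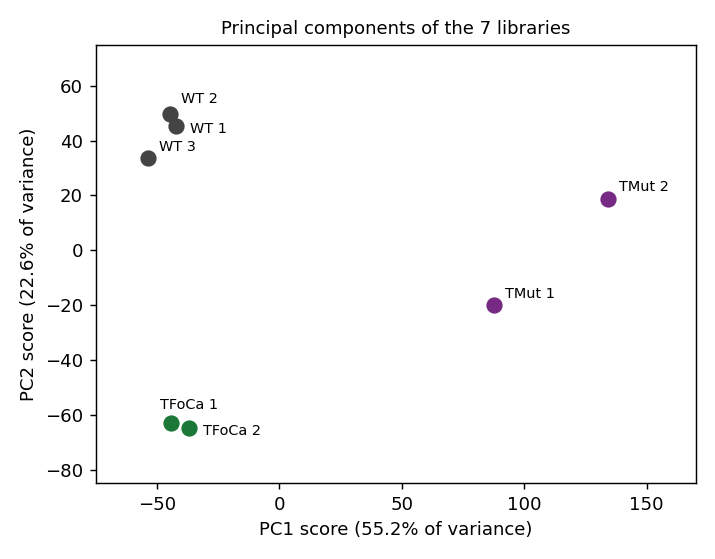
Principal component scores of the 7 libraries, 1 point per library, coloured by genotype; the axes give scores without units and the share of variance. Both TMut libraries lie at 87.7 or more on the first component, and the other 5 libraries at -37.1 or less.

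The comparison of TFoCa with WT asks what the TFoCa genotype changes in neural stem cells. TFoCa lines had less RNA of pluripotency and cell cycle genes and more RNA of mesenchymal and extracellular matrix genes. Nanog, a transcription factor of pluripotent cells, had a log2 fold change of -3.53 ± 0.35 (adjusted p = 0.0029), and Pcna, the DNA polymerase clamp, one of -1.02 ± 0.12 (adjusted p = 0.0043). Fn1, which encodes fibronectin, rose by 1.76 ± 0.12 log2 units (adjusted p = 0.0012). In all, 952 genes rose and 638 fell, and 551 of the former and 259 of the latter changed by at least 1 log2 unit. The largest rises by the naming rule were those of Cxcl15 (4.25 ± 0.49), a chemokine gene, Inhba (4.20 ± 0.46), which encodes an activin subunit, and Ptgs2 (4.18 ± 0.27), a prostaglandin synthase gene. Its largest falls were those of Zscan4c (-5.55 ± 0.94), Slc28a1 (-5.50 ± 0.63) and Prdm14 (-5.44 ± 0.55). Reads of Zscan4c cannot be told from those of its near-identical paralogs in this table. Zscan4c lost its call without WT replicate 1 (adjusted p = 0.0525) and WT replicate 2 (adjusted p = 0.0568), and with voom (adjusted p = 0.093). Zscan4c lay at -3.53 with a pseudocount of 8. Slc28a1 lost its call with voom (adjusted p = 0.0519).

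Of 25 measured pluripotency genes, 1 rose and 19 fell (median log2 fold change -3.53, camera adjusted p = 5.98e-14, adjusted p = 0.358 with an estimated correlation). Nanog (-3.53 ± 0.35) and Prdm14 (-5.44 ± 0.55) had the smallest adjusted p values, and adjusted over the list alone 2 rose and 22 fell. The member that rose was Klf4 (0.88), named after its values were seen. Klf4 lost its call without WT replicate 1 (adjusted p = 0.0613), WT replicate 2 (adjusted p = 0.0644), WT replicate 3 (adjusted p = 0.0615), TFoCa replicate 1 (adjusted p = 0.0692) and TFoCa replicate 2 (adjusted p = 0.0504). Of 28 measured germline genes of the promoter methylation list, 0 rose and 4 fell (median log2 fold change -1.65, camera adjusted p = 0.000485, adjusted p = 0.549 with an estimated correlation and adjusted p = 0.157 by fry). Rpl10l (at most -5.84 log2 units, from the floor), whose reads can be shared with its parent gene Rpl10, and Rhox9 (-3.76 ± 0.63) led the list, and adjusted over the list alone 0 rose and 9 fell. Without TFoCa replicate 1 (median -0.81, adjusted p = 0.136) the list call ended. The median was -0.96 with a pseudocount of 8. Rhox9 lost its call with voom (adjusted p = 0.0666). Rhox9 lay at -2.32 with a pseudocount of 8. Of 36 measured replication and S phase genes, 0 rose and 23 fell (median log2 fold change -0.67, camera adjusted p = 2.5e-18, adjusted p = 0.358 with an estimated correlation). Pcna (-1.02 ± 0.12) and Mcm7 (-0.95 ± 0.11), a subunit of the replicative helicase, had the smallest adjusted p values, and adjusted over the list alone 0 rose and 35 fell. Of 36 measured mitosis genes, 0 rose and 23 fell (median log2 fold change -0.52, camera adjusted p = 4.99e-16, adjusted p = 0.358 with an estimated correlation). Mad2l1 (-0.74 ± 0.11), of the spindle checkpoint, and Ccna2 (-0.60 ± 0.09), which encodes cyclin A2, led this list, and adjusted over the list alone 0 rose and 29 fell.

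Of 30 measured mesenchymal and fibroblast genes, 20 rose and 0 fell (median log2 fold change 1.30, camera adjusted p = 2.5e-18, adjusted p = 0.358 with an estimated correlation). Fn1 (1.76 ± 0.12) and Lox (2.40 ± 0.19), a collagen crosslinking enzyme, had the smallest adjusted p values, and adjusted over the list alone 27 rose and 0 fell. Of 69 measured extracellular matrix and adhesion genes, 20 rose and 3 fell (median log2 fold change 0.64, camera adjusted p = 3.34e-09, adjusted p = 0.358 with an estimated correlation). Itga1 (2.48 ± 0.16), a collagen receptor subunit, and Sparc (1.27 ± 0.10), a matrix glycoprotein, led the list, and adjusted over the list alone 34 rose and 5 fell. The median was 0.30 without TFoCa replicate 1. Of 16 measured neural crest and Schwann genes, 4 rose and 0 fell (median log2 fold change 0.34, camera adjusted p = 0.0118, adjusted p = 0.358 with an estimated correlation). Ets1 (1.02 ± 0.11) and Snai2 (1.93 ± 0.21), both transcription factors, had the smallest adjusted p values, and adjusted over the list alone 4 rose and 1 fell. Without TFoCa replicate 2 (median 0.19, adjusted p = 0.165) the list call ended. The median was 0.75 without TFoCa replicate 1. Of 35 measured BMP and TGF-beta signalling genes, 12 rose and 0 fell (median log2 fold change 0.45, camera adjusted p = 1.37e-06, adjusted p = 0.358 with an estimated correlation). Inhbb (1.71 ± 0.14) and Tgfb2 (1.47 ± 0.14), both ligand genes, led the list, and adjusted over the list alone 14 rose and 0 fell. The median was 0.95 without TFoCa replicate 2. Of 39 measured axon guidance genes, 9 rose and 0 fell (median log2 fold change 0.54, camera adjusted p = 1.04e-05, adjusted p = 0.358 with an estimated correlation). Sema3a (2.48 ± 0.23) and Nrp1 (0.95 ± 0.11), a ligand and its receptor, led this group, and adjusted over the list alone 11 rose and 2 fell. The median was 0.29 without TFoCa replicate 1.

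Of 28 measured immediate early genes, 8 rose and 0 fell (median log2 fold change 0.53, camera adjusted p = 4.5e-06, adjusted p = 0.358 with an estimated correlation). Fosl2 (1.96 ± 0.18) and Myc (1.32 ± 0.16), both transcription factors, had the smallest adjusted p values, and adjusted over the list alone 14 rose and 0 fell. Of 26 measured p53 targets, 4 rose and 0 fell (median log2 fold change 0.21, camera adjusted p = 0.034, adjusted p = 0.549 with an estimated correlation and adjusted p = 0.132 by fry). Plk2 (1.53 ± 0.19) and Cdkn1a (0.75 ± 0.09), which encodes the p21 cell cycle inhibitor, led the list, and adjusted over the list alone 6 rose and 2 fell. Without WT replicate 2 (median 0.19, adjusted p = 0.055) or TFoCa replicate 2 (median -0.01, adjusted p = 0.483) the list call ended. The median was 0.40 without TFoCa replicate 1. Of 31 measured interferon response genes, 0 rose and 0 fell (median log2 fold change 0.36, camera adjusted p = 0.00846, adjusted p = 0.624 with an estimated correlation and adjusted p = 0.356 by fry). Ifi35 (1.27 ± 0.32) and Oas1a (-2.34 ± 0.61), neither of them called, had the smallest adjusted p values, and adjusted over the list alone 0 rose and 0 fell. Without WT replicate 1 (median 0.17, adjusted p = 0.0727) or TFoCa replicate 2 (median 0.06, adjusted p = 0.625) the list call ended. The median was 0.57 without WT replicate 2 and 0.93 without TFoCa replicate 1. Ifi35 was called without TFoCa replicate 1 (1.72, adjusted p = 0.0237), and at a mean of 50 or more (adjusted p = 0.0487), with TMM factors (adjusted p = 0.0461), with robust eBayes (adjusted p = 0.0496), with edgeR (adjusted p = 0.0387), with DESeq2 (adjusted p = 0.00131) and with thinned libraries (adjusted p = 0.0462). Oas1a was called without TFoCa replicate 2 (-3.28, adjusted p = 0.0171), and with DESeq2 (adjusted p = 0.0224). Of 21 measured telencephalic patterning genes, 0 rose and 7 fell (median log2 fold change -0.70, camera adjusted p = 6.98e-05, adjusted p = 0.469 with an estimated correlation and adjusted p = 0.0855 by fry). Emx1 (-3.78 ± 0.51) and Zic2 (-1.15 ± 0.16), both forebrain transcription factors, led the list, and adjusted over the list alone 0 rose and 9 fell. The median was -0.29 without TFoCa replicate 1 and -1.27 without TFoCa replicate 2. Of 35 measured neuronal differentiation genes, 0 rose and 1 fell (median log2 fold change -0.28, camera adjusted p = 0.0339, adjusted p = 0.726 with an estimated correlation and adjusted p = 0.453 by fry). Ina (-0.71 ± 0.12), a neurofilament gene, was called and Neurod6 (-2.63 ± 0.72) was not, and adjusted over the list alone 0 rose and 1 fell. Without TFoCa replicate 1 (median -0.32, adjusted p = 0.326) the list call ended. Ina lost its call without WT replicate 2 (adjusted p = 0.0532) and WT replicate 3 (adjusted p = 0.0543). Neurod6 was called without TMut replicate 1 (adjusted p = 0.0407) and TMut replicate 2 (adjusted p = 0.0387), and with a pseudocount of 8 (adjusted p = 0.0281), with quantile normalization (adjusted p = 0.0483), with edgeR (adjusted p = 0.0492), with DESeq2 (adjusted p = 0.000654) and in a fit to these 2 genotypes (adjusted p = 0.0354).

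Of 25 measured cholesterol synthesis genes, 0 rose and 0 fell (median log2 fold change -0.56, camera adjusted p = 1.68e-05, adjusted p = 0.544 with an estimated correlation and adjusted p = 0.212 by fry). Idi1 (-1.05 ± 0.33) and Fdft1 (-0.55 ± 0.18), neither of them called, had the smallest adjusted p values, and adjusted over the list alone 0 rose and 0 fell. The median was -0.34 without WT replicate 1. Idi1 was called with DESeq2 (adjusted p = 0.00726). Fdft1 was called with DESeq2 (adjusted p = 0.0346). Of 36 measured oxidative phosphorylation genes, 0 rose and 2 fell (median log2 fold change -0.15, camera adjusted p = 0.000436, adjusted p = 0.389 with an estimated correlation). Cox5a (-0.50 ± 0.09) and Ndufa4 (-0.49 ± 0.11) were the called members, and adjusted over the list alone 0 rose and 1 fell. Cox5a lost its call without WT replicate 1 (adjusted p = 0.0576), WT replicate 2 (adjusted p = 0.0862) and WT replicate 3 (adjusted p = 0.059). Ndufa4 lost its call without WT replicate 1 (adjusted p = 0.11), WT replicate 2 (adjusted p = 0.0835), WT replicate 3 (adjusted p = 0.116), TFoCa replicate 2 (adjusted p = 0.113), TMut replicate 1 (adjusted p = 0.0535) and TMut replicate 2 (adjusted p = 0.0538), and with edgeR (adjusted p = 0.052), with voom (adjusted p = 0.0554) and in a fit to these 2 genotypes (adjusted p = 0.0555). Of 35 measured Polycomb and chromatin regulator genes, 0 rose and 3 fell (median log2 fold change -0.14, camera adjusted p = 0.00925, adjusted p = 0.358 with an estimated correlation). Ezh2 (-0.66 ± 0.12), the histone methyltransferase, and Rbbp4 (-0.43 ± 0.09) led the list, and adjusted over the list alone 0 rose and 5 fell. Without TFoCa replicate 1 (median -0.17, adjusted p = 0.122) the list call ended. The median was -0.23 without TFoCa replicate 2. Ezh2 lost its call without WT replicate 1 (adjusted p = 0.0502), WT replicate 2 (adjusted p = 0.0534), WT replicate 3 (adjusted p = 0.0659) and TFoCa replicate 1 (adjusted p = 0.0507). Rbbp4 lost its call without WT replicate 1 (adjusted p = 0.0703), WT replicate 2 (adjusted p = 0.0822) and WT replicate 3 (adjusted p = 0.101). Of 20 measured DNA methylation writers and readers, 1 rose and 5 fell (median log2 fold change -0.23, camera adjusted p = 0.034, adjusted p = 0.358 with an estimated correlation). Dnmt1 (-0.51 ± 0.09), the maintenance methyltransferase, and Ctcf (-0.49 ± 0.09) led this group, and adjusted over the list alone 2 rose and 8 fell. Without TFoCa replicate 2 (median -0.14, adjusted p = 0.191) the list call ended. Dnmt1 lost its call without WT replicate 2 (adjusted p = 0.0608) and WT replicate 3 (adjusted p = 0.0615). Ctcf lost its call without WT replicate 1 (adjusted p = 0.0663), WT replicate 2 (adjusted p = 0.0573), WT replicate 3 (adjusted p = 0.0866) and TFoCa replicate 1 (adjusted p = 0.0511). Its member that rose was Zbtb4 (0.81 ± 0.17), named after its values were seen. Zbtb4 lost its call without WT replicate 1 (adjusted p = 0.0701), WT replicate 2 (adjusted p = 0.0883), WT replicate 3 (adjusted p = 0.094) and TFoCa replicate 2 (adjusted p = 0.0846).

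RNA of the TET genes and of Tdg, which encodes the glycosylase that removes formyl- and carboxylcytosine, did not pass the test between TFoCa and WT. Tet1 had a log2 fold change of -0.21 ± 0.28 (adjusted p = 0.69), Tet2 of 0.88 ± 0.26 (adjusted p = 0.074), Tet3 of 0.15 ± 0.16 (adjusted p = 0.61) and Tdg of -0.30 ± 0.09 (adjusted p = 0.075). Tet2 was called without TFoCa replicate 2 (1.38, adjusted p = 0.00471), and with DESeq2 (adjusted p = 0.00444). Tdg was called with DESeq2 (adjusted p = 0.0367). Of the 4 genes of the TET and TDG list, 0 rose and 0 fell (median log2 fold change -0.03, camera adjusted p = 0.957, adjusted p = 0.977 with an estimated correlation and adjusted p = 0.809 by fry), and adjusted over the list alone Tet2 rose and Tdg fell. The number of changed genes depended on the WT lines: it was 734 without WT replicate 1, 495 without WT replicate 2 and 638 without WT replicate 3, against 1590 with all libraries. Among the 127 called genes that the naming rule takes for this comparison, 54 (42.5%) lost their call when some library was left out.

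**Figure D2:**
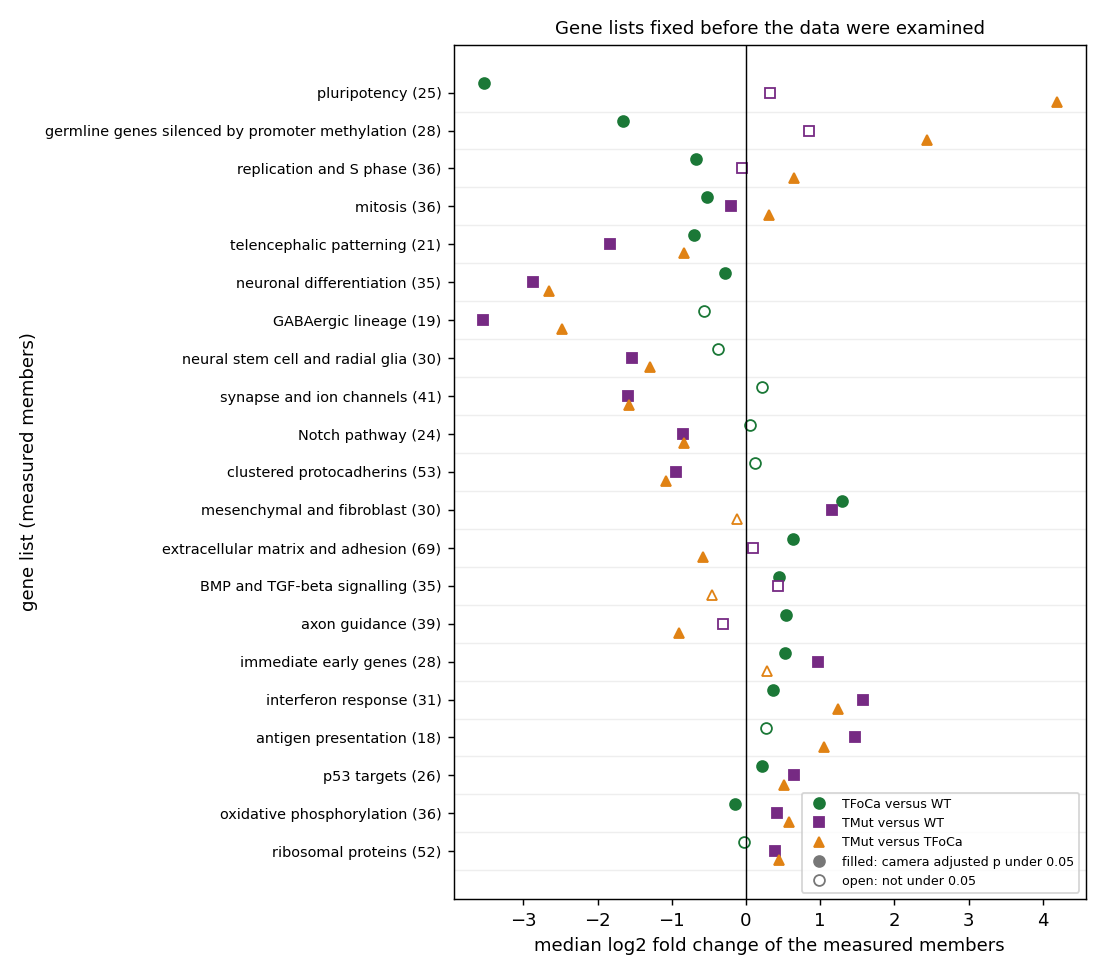
Median log2 fold change of the measured members (horizontal axis) of 21 gene lists, 1 symbol per comparison, with the number of measured members in brackets. Filled symbols have a camera adjusted p under 0.05 with the preset correlation, and none has with an estimated one; the pluripotency list lies at -3.53 in TFoCa versus WT and the neuronal list at -2.86 in TMut versus WT.

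The comparison of TMut with WT asks the same of the TMut genotype. TMut lines had less RNA of neuronal, glial and forebrain patterning genes and more RNA of mesenchymal, interferon response and antigen presentation genes. Ina, a neurofilament gene, fell by 2.45 ± 0.12 log2 units (adjusted p = 4.7e-05). Mlc1, an astrocyte membrane protein gene, fell by 5.61 ± 0.26 (adjusted p = 4.3e-05), and B2m, the light chain of MHC class I, rose by 1.83 ± 0.11 (adjusted p = 7.4e-05). In all, 3344 genes rose and 3699 fell, and 1380 and 2192 of these changed by at least 1 log2 unit. By the naming rule the largest rises were those of Slfn2, Gzme and Aspn (6.68 ± 0.84). All WT libraries were at 0 for Slfn2 and Gzme, so their rises were at least 7.46 and 7.07 log2 units against a floor of 3 reads over the group; with 1 TMut library left out they fell below the filter and were not tested. The largest falls were those of Lrrtm2, a synaptic adhesion gene, Igfbp1 and Slc39a12, all at 0 in both TMut libraries, which puts their log2 fold changes at -7.14, -6.89 and -6.39 or lower. Without WT replicate 3 the limit for Igfbp1 was -5.76.

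Of 35 measured neuronal differentiation genes, 1 rose and 31 fell (median -2.86, camera adjusted p = 5.24e-13, adjusted p = 0.358 with an estimated correlation). Ina (-2.45 ± 0.12) and Celf4 (-2.81 ± 0.22), a neuronal RNA-binding protein, had the smallest adjusted p values, and adjusted over the list alone 1 rose and 33 fell. Of 19 measured GABAergic lineage genes, 1 rose and 14 fell (median -3.55, camera adjusted p = 2.23e-06, adjusted p = 0.389 with an estimated correlation). Gsx1 (-3.67 ± 0.31) and Dlx2 (-3.34 ± 0.29), both homeobox genes of the ventral forebrain, led the list, and adjusted over the list alone 2 rose and 16 fell. Of 41 measured synapse and ion channel genes, 1 rose and 26 fell (median -1.58, camera adjusted p = 3.49e-07, adjusted p = 0.389 with an estimated correlation). Gria1 (-3.28 ± 0.22), a glutamate receptor subunit, and Dlg2 (-3.53 ± 0.30), a postsynaptic scaffold, led the list, and adjusted over the list alone 1 rose and 27 fell. Of 30 measured neural stem cell and radial glia genes, 3 rose and 21 fell (median -1.53, camera adjusted p = 1.27e-06, adjusted p = 0.389 with an estimated correlation). Slc1a3 (-2.59 ± 0.18), a glial glutamate transporter, and Emx2 (-2.35 ± 0.16), a cortical transcription factor, had the smallest adjusted p values, and adjusted over the list alone 3 rose and 22 fell. Of 23 measured astrocyte genes, 4 rose and 13 fell (median -0.66, camera adjusted p = 0.0317, adjusted p = 0.358 with an estimated correlation). Mlc1 (-5.61 ± 0.26) and Slc1a2 (-3.54 ± 0.35), a glutamate transporter, led this group, and adjusted over the list alone 4 rose and 13 fell. Without WT replicate 1 (median -0.66, adjusted p = 0.0511) the list call ended.

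Of 20 measured oligodendrocyte lineage genes, 1 rose and 13 fell (median -1.51, camera adjusted p = 0.00386, adjusted p = 0.358 with an estimated correlation). Nkx6-2 (-4.11 ± 0.27) and Cldn11 (-4.46 ± 0.49), a myelin tight junction gene, had the smallest adjusted p values, and adjusted over the list alone 2 rose and 13 fell. Of 21 measured telencephalic patterning genes, 0 rose and 16 fell (median -1.83, camera adjusted p = 2.76e-08, adjusted p = 0.358 with an estimated correlation). Emx2 (-2.35 ± 0.16) and Otx1 (-3.71 ± 0.26), both homeobox genes, led the list, and adjusted over the list alone 0 rose and 18 fell. Of 23 measured caudal patterning genes, 3 rose and 11 fell (median -0.96, camera adjusted p = 0.0066, adjusted p = 0.358 with an estimated correlation). Otx2 (-2.07 ± 0.15) and Barhl2 (-4.33 ± 0.36) led that list, and adjusted over the list alone 3 rose and 12 fell. Whether this list tracks caudal identity was not tested. Of 53 measured clustered protocadherin genes, 1 rose and 28 fell (median -0.95, camera adjusted p = 2.21e-06, adjusted p = 0.358 with an estimated correlation). Pcdhb13 (-4.59 ± 0.63) and Pcdha12 (-2.83 ± 0.47), adhesion molecules of neurons, had the smallest adjusted p values, and adjusted over the list alone 1 rose and 32 fell. Pcdhb13 lay at -2.50 with a pseudocount of 8. Of 15 measured ependymal and choroid plexus genes, 0 rose and 5 fell (median -0.67, camera adjusted p = 0.0498, adjusted p = 0.358 with an estimated correlation). Otx2 (-2.07 ± 0.15), also on the caudal list, and Foxj1 (-1.86 ± 0.36), a regulator of motile cilia, led this group. Adjusted over the list alone 0 rose and 5 fell. The list call ended without WT replicate 2 (median -0.84, adjusted p = 0.0644) and without TFoCa replicate 1 or 2 (median -0.67). It ended too without TMut replicate 1 (median -0.65) or 2 (median -1.20). It also ended with a pseudocount of 8 (median -0.61, adjusted p = 0.0543), with quantile normalization (median -0.49, adjusted p = 0.0835) and with thinned libraries (median -0.69, adjusted p = 0.0545).

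Of 24 measured Notch pathway genes, 0 rose and 14 fell (median -0.85, camera adjusted p = 8.11e-05, adjusted p = 0.358 with an estimated correlation). Dtx4 (-1.94 ± 0.17) and Dll3 (-2.77 ± 0.27), a Notch ligand gene, had the smallest adjusted p values, and adjusted over the list alone 0 rose and 16 fell. Of 38 measured Wnt signalling genes, 5 rose and 18 fell (median -0.64, camera adjusted p = 0.00794, adjusted p = 0.358 with an estimated correlation). Fzd9 (-3.03 ± 0.23), a receptor, and Wnt7b (-5.59 ± 0.46), a ligand, led the list, and adjusted over the list alone 5 rose and 18 fell. The median was -1.18 without TMut replicate 1 and -0.34 without TMut replicate 2. Of 36 measured mitosis genes, 2 rose and 10 fell (median -0.20, camera adjusted p = 0.0101, adjusted p = 0.645 with an estimated correlation and adjusted p = 0.069 by fry). Prc1 (-0.88 ± 0.09) and Nusap1 (-0.93 ± 0.10), both spindle proteins, led this list, and adjusted over the list alone 2 rose and 10 fell. Without WT replicate 1 (median -0.14, adjusted p = 0.0716) the list call ended. Of 35 measured Polycomb and chromatin regulator genes, 2 rose and 6 fell (median -0.15, camera adjusted p = 0.0485, adjusted p = 0.389 with an estimated correlation). Chd7 (-1.21 ± 0.11) and Ezh2 (-0.89 ± 0.12) led that group, and adjusted over the list alone 2 rose and 6 fell. Without WT replicate 2 (median -0.17, adjusted p = 0.0535), WT replicate 3 (median -0.13, adjusted p = 0.0605) or TMut replicate 1 (median -0.20, adjusted p = 0.174) the list call ended. Of 27 measured Hox genes, 1 rose and 1 fell (median 1.25, camera adjusted p = 0.0252, adjusted p = 0.505 with an estimated correlation and adjusted p = 0.0992 by fry). Hoxb1 (-2.32 ± 0.68) and Hoxb9 (1.89 ± 0.62) were the called members, and adjusted over the list alone 0 rose and 0 fell. Without WT replicate 3 (median 0.97, adjusted p = 0.0605) or TMut replicate 1 (median 1.57, adjusted p = 0.058) the list call ended. Hoxb1 lost its call without WT replicate 1 (adjusted p = 0.0639), WT replicate 2 (adjusted p = 0.0875), WT replicate 3 (adjusted p = 0.0711) and TMut replicate 2 (adjusted p = 0.167), and with voom (adjusted p = 0.0541). Hoxb9 lost its call without WT replicate 2 (adjusted p = 0.0917), WT replicate 3 (adjusted p = 0.112), TMut replicate 1 (adjusted p = 0.0516) and TMut replicate 2 (adjusted p = 0.241).

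Of 30 measured mesenchymal and fibroblast genes, 18 rose and 4 fell (median 1.17, camera adjusted p = 1.26e-05, adjusted p = 0.358 with an estimated correlation). Fn1 (2.11 ± 0.12) and Loxl1 (2.29 ± 0.14), a collagen and elastin crosslinking enzyme, had the smallest adjusted p values, and adjusted over the list alone 19 rose and 5 fell. The members that fell, named after their values were seen, were Col1a1 (-0.72), Col5a2 (-1.39), Pdgfrb (-0.63) and Fbln2 (-1.83). Col1a1 lost its call without WT replicate 1 (adjusted p = 0.0842), WT replicate 2 (adjusted p = 0.108), WT replicate 3 (adjusted p = 0.101) and TMut replicate 2 (-0.28, adjusted p = 0.239), and with edgeR (adjusted p = 0.0694). Col1a1 lay at -1.16 without TMut replicate 1. Col5a2 lost its call without WT replicate 3 (adjusted p = 0.0511) and TMut replicate 2 (adjusted p = 0.0908). Pdgfrb lost its call without TMut replicate 2 (adjusted p = 0.0696). Fbln2 lost its call without TMut replicate 2 (adjusted p = 0.0552). Of 16 measured neural crest and Schwann genes, 6 rose and 2 fell (median 0.85, camera adjusted p = 0.017, adjusted p = 0.358 with an estimated correlation). Ets1 (1.91 ± 0.11) and Snai2 (3.01 ± 0.21) led the list, and adjusted over the list alone 7 rose and 2 fell. Without TMut replicate 2 (median 0.15, adjusted p = 0.0809) the list call ended.

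Of 31 measured interferon response genes, 16 rose and 0 fell (median 1.57, camera adjusted p = 2.09e-06, adjusted p = 0.412 with an estimated correlation). Irf1 (2.29 ± 0.24), a transcription factor, and Ifi35 (2.503 ± 0.32) had the smallest adjusted p values, and adjusted over the list alone 18 rose and 0 fell. Of 18 measured antigen presentation genes, 11 rose and 1 fell (median 1.47, camera adjusted p = 0.000127, adjusted p = 0.358 with an estimated correlation). B2m (1.83 ± 0.11) and Tap2 (1.56 ± 0.15), a peptide transporter subunit, led the list, and adjusted over the list alone 14 rose and 1 fell. Of 26 measured p53 targets, 14 rose and 1 fell (median 0.65, camera adjusted p = 0.000196, adjusted p = 0.389 with an estimated correlation). Cdkn1a (1.33 ± 0.09) and Tnfrsf10b (1.61 ± 0.16), a death receptor gene, led this list, and adjusted over the list alone 15 rose and 1 fell. Of 28 measured immediate early genes, 16 rose and 2 fell (median 0.97, camera adjusted p = 0.000424, adjusted p = 0.358 with an estimated correlation). Myc (2.01 ± 0.16) and Fosl2 (1.90 ± 0.18) led that list, and adjusted over the list alone 17 rose and 2 fell.

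Of 36 measured oxidative phosphorylation genes, 22 rose and 1 fell (median 0.42, camera adjusted p = 1.11e-06, adjusted p = 0.358 with an estimated correlation). Uqcrfs1 (-0.80 ± 0.09), its member that fell, and Cox8a (0.72 ± 0.09) had the smallest adjusted p values, and adjusted over the list alone 22 rose and 1 fell. Genes of the mitochondrial genome held 1.053% and 1.111% of reads in the TMut libraries, against 0.7805% to 0.9253% in the other 5, and so moved with this list. Of 52 measured ribosomal protein genes, 23 rose and 0 fell (median 0.39, camera adjusted p = 5.4e-08, adjusted p = 0.544 with an estimated correlation and adjusted p = 0.0596 by fry). Rpl41 (0.79 ± 0.12) and Rplp1 (0.72 ± 0.15) led this group, and adjusted over the list alone 35 rose and 0 fell. The median was 0.14 with quantile normalization. Rplp1 lost its call without TMut replicate 2 (adjusted p = 0.0687). Rplp1 lay at 0.47 with quantile normalization. After removal of the trend of fold changes with transcript length, GC content and mean level, the median was 0.02 for the ribosomal list and 0.13 for the oxidative phosphorylation list. With transcript length and GC content alone removed, the medians were 0.33 and 0.40.

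In several lists 1 member alone was called against the direction of the rest, and these are named after their values were seen. They were Nefh (1.70), Lhx6 (1.79), Cnp (1.08), Gria3 (1.03), Pcdhgc5 (0.72), H2-K1 (-0.65) and Plk3 (-0.71). Nefh lost its call without WT replicate 1 (adjusted p = 0.0813), WT replicate 3 (adjusted p = 0.0898) and TMut replicate 2 (0.86, adjusted p = 0.184). Pcdhgc5 lost its call without WT replicate 1 (adjusted p = 0.0671), WT replicate 2 (adjusted p = 0.105), WT replicate 3 (adjusted p = 0.109), TMut replicate 1 (adjusted p = 0.0615) and TMut replicate 2 (adjusted p = 0.152). Tdg fell by 0.66 ± 0.09 log2 units (adjusted p = 0.0011). The TET genes did not pass the test, with log2 fold changes of 0.25 ± 0.28 for Tet1 (adjusted p = 0.52), -0.19 ± 0.26 for Tet2 (adjusted p = 0.6) and -0.31 ± 0.16 for Tet3 (adjusted p = 0.17). Tet1 was called without TMut replicate 1 (0.82, adjusted p = 0.00394). Tet3 was called without TMut replicate 1 (-0.55, adjusted p = 0.0382). Of the 4 genes of the TET and TDG list, 0 rose and 1 fell (median -0.25, camera adjusted p = 0.342, adjusted p = 0.544 with an estimated correlation and adjusted p = 0.02 by fry, which calls it), and adjusted over the list alone Tdg fell. The number of changed genes was 4329 without TMut replicate 2, against 7043 with all libraries. Among the 171 called genes that the naming rule takes here, 24 (14%) lost their call when some library was left out.

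The pluripotency and germline lists did not pass the camera test between TMut and WT with all libraries, but did in some alternatives. Of 25 measured pluripotency genes, 4 rose and 1 fell, also adjusted over the list alone (median 0.32, camera adjusted p = 0.221, adjusted p = 0.868 with an estimated correlation). The list was called without TMut replicate 1 (median 1.02, adjusted p = 0.000509) and WT replicate 2 (median 0.48, adjusted p = 0.0496), and its median was -0.22 without TMut replicate 2 (adjusted p = 0.619) and 0.21 without WT replicate 1 (adjusted p = 0.562). Tfcp2l1 fell by 1.22 ± 0.30 and Tdgf1 rose by 2.09 ± 0.54 log2 units. Tfcp2l1 lost its call without WT replicate 2 (adjusted p = 0.0512) and TMut replicate 1 (adjusted p = 0.0868). Tdgf1 lost its call without WT replicate 1 (adjusted p = 0.0547), WT replicate 3 (adjusted p = 0.0629) and TMut replicate 2 (1.05, adjusted p = 0.068). Of 28 measured germline genes, 6 rose and 1 fell (median 0.85, camera adjusted p = 0.0546, adjusted p = 0.738 with an estimated correlation). That list was called without TMut replicate 1 (median 1.95, adjusted p = 0.00098), WT replicate 2 (median 1.05, adjusted p = 0.00992), TFoCa replicate 1 (adjusted p = 0.0455) and TFoCa replicate 2 (adjusted p = 0.0467), with quantile normalization (adjusted p = 0.0329) and with a pseudocount of 8 (adjusted p = 0.0391), and its median was 0.11 without TMut replicate 2 (adjusted p = 0.585). Taf7l (3.47 ± 0.89) and Dnmt3l (2.16 ± 0.60) had the smallest adjusted p values, and adjusted over the list alone 0 rose and 0 fell. Taf7l lost its call without WT replicate 3 (adjusted p = 0.0577) and TMut replicate 2 (adjusted p = 0.128). Dnmt3l lost its call without WT replicate 1 (adjusted p = 0.0696), WT replicate 3 (adjusted p = 0.0674) and TMut replicate 2 (1.14, adjusted p = 0.148).

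**Figure D3:**
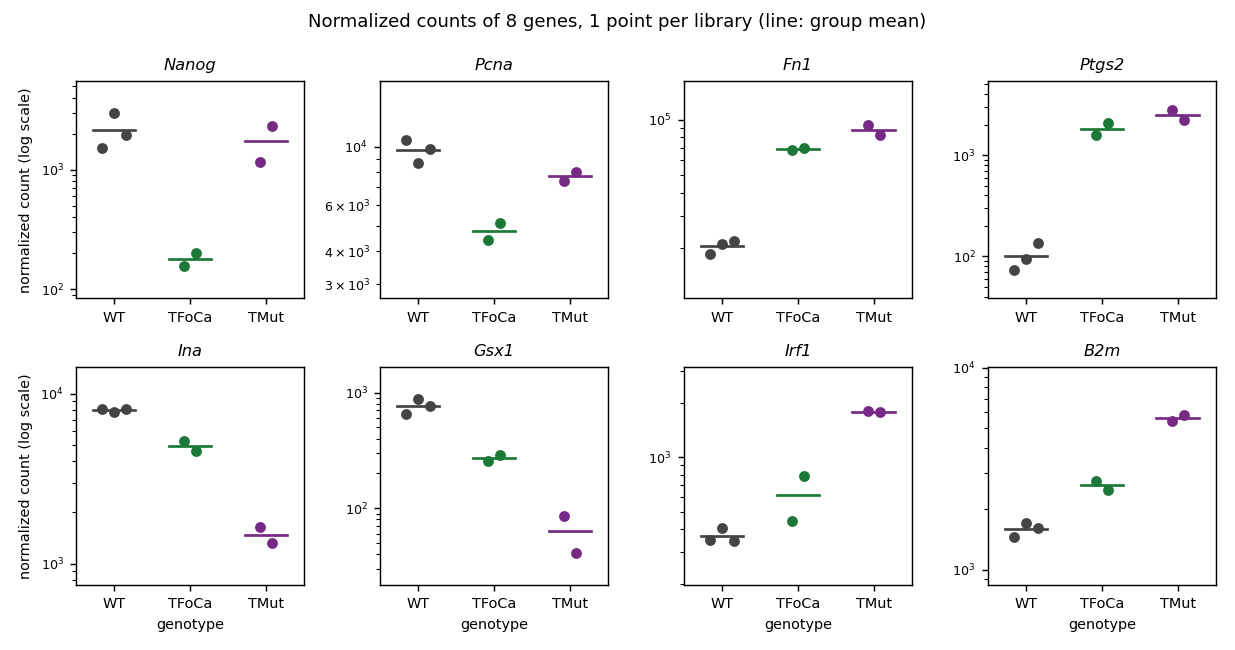
Normalized counts (vertical log axis) of 8 genes in each library, 1 point per library, by genotype; the line is the group mean. Nanog and Pcna are lowest in TFoCa, Ina and Gsx1 lowest in TMut, and Fn1 and Ptgs2 higher in both mutant genotypes than in WT.

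The direct comparison of TMut with TFoCa asks where the mutant genotypes differ from each other. Pluripotency, replication and oxidative phosphorylation genes were higher in TMut, and neuronal, synaptic and protocadherin genes were higher in TFoCa. Tdgf1, a gene of pluripotent cells, was higher in TMut by 5.36 ± 0.60 log2 units (adjusted p = 0.0017) and Ccne1, which encodes cyclin E1, by 1.84 ± 0.16 (adjusted p = 0.0014). Ina was lower by 1.74 ± 0.13 (adjusted p = 0.0012). In all, 3141 genes were higher and 3350 lower in TMut, 1074 and 2176 of them by at least 1 log2 unit. By the naming rule the largest rises were those of Rpl10l, at 0 in both TFoCa libraries and so at least 6.61 log2 units higher, Dppa2 (6.69 ± 0.85) and AU015836 (6.66 ± 0.82). The largest falls were those of Ferd3l, at 0 in both TMut libraries and so at a log2 fold change of -6.26 or lower, Corin (-6.81 ± 0.67) and Adra1a (-6.13 ± 0.92). The limit for Rpl10l was 4.98 without TMut replicate 2 and 7.35 without TMut replicate 1, and that for Ferd3l -5.25 without TFoCa replicate 1 and -6.85 without TFoCa replicate 2. AU015836 lay at 4.34 with a pseudocount of 8.

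Of 25 measured pluripotency genes, 22 rose and 1 fell (median 4.19, camera adjusted p = 8.13e-10, adjusted p = 0.389 with an estimated correlation). Tdgf1 (5.36 ± 0.60) and Utf1 (6.58 ± 0.75) had the smallest adjusted p values, and adjusted over the list alone 23 rose and 1 fell. The member that fell was Klf4 (-0.79), named after its values were seen. Klf4 lost its call without TFoCa replicate 1 (adjusted p = 0.0584) and TMut replicate 1 (adjusted p = 0.0756). Of 28 measured germline genes, 15 rose and 0 fell (median 2.44, camera adjusted p = 2.34e-05, adjusted p = 0.505 with an estimated correlation and adjusted p = 0.0621 by fry). Rpl10l (at least 6.61 log2 units, from the floor) and Dnmt3l (4.90 ± 0.66), a methyltransferase cofactor, led the list, and adjusted over the list alone 18 rose and 2 fell. The median was 1.42 without TMut replicate 2. Of 36 measured replication and S phase genes, 22 rose and 0 fell (median 0.65, camera adjusted p = 9.02e-10, adjusted p = 0.389 with an estimated correlation). Ccne1 (1.84 ± 0.16) and Tyms (1.37 ± 0.16), thymidylate synthase, led this list, and adjusted over the list alone 29 rose and 0 fell. Of 36 measured mitosis genes, 16 rose and 1 fell (median 0.32, camera adjusted p = 0.0017, adjusted p = 0.553 with an estimated correlation and adjusted p = 0.0762 by fry). Cdk1 (1.04 ± 0.17), the mitotic kinase, and Mad2l1 (0.75 ± 0.12) led that list, and adjusted over the list alone 16 rose and 2 fell. The member that fell was Prc1 (-0.45), named after its values were seen. Prc1 lost its call without TMut replicate 2 (adjusted p = 0.08), and in a fit to these 2 genotypes (adjusted p = 0.0679).

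Of 36 measured oxidative phosphorylation genes, 29 rose and 1 fell (median 0.58, camera adjusted p = 9.02e-10, adjusted p = 0.358 with an estimated correlation). Cox7b (1.22 ± 0.14) and Cox8a (0.83 ± 0.09), both of cytochrome c oxidase, had the smallest adjusted p values, and adjusted over the list alone 29 rose and 1 fell. Uqcrfs1 (-0.68), the member that fell, is named after its values were seen. The share of mitochondrial reads was also higher in TMut (1.053% and 1.111%, against 0.8419% and 0.9253% in TFoCa). Of 52 measured ribosomal protein genes, 24 rose and 0 fell (median 0.45, camera adjusted p = 1.54e-08, adjusted p = 0.53 with an estimated correlation and adjusted p = 0.0645 by fry). Rpl41 (0.85 ± 0.13) and Rplp2 (0.62 ± 0.12) led the list, and adjusted over the list alone 33 rose and 0 fell. The median was 0.20 with quantile normalization and 0.27 without TFoCa replicate 1. Rplp2 lay at 0.39 with quantile normalization. Of 25 measured cholesterol synthesis genes, 6 rose and 0 fell (median 0.58, camera adjusted p = 0.00115, adjusted p = 0.649 with an estimated correlation and adjusted p = 0.206 by fry). Fdps (1.31 ± 0.26) and Ebp (0.66 ± 0.15) led this group, and adjusted over the list alone 3 rose and 0 fell. Ebp lost its call without TMut replicate 1 (adjusted p = 0.0583), and in a fit to these 2 genotypes (adjusted p = 0.0651). Of 31 measured interferon response genes, 11 rose and 0 fell (median 1.24, camera adjusted p = 0.000457, adjusted p = 0.527 with an estimated correlation and adjusted p = 0.12 by fry). Irf1 (1.59 ± 0.26) and Oas1a (3.38 ± 0.67) led that group, and adjusted over the list alone 11 rose and 0 fell. The median was 0.79 without TFoCa replicate 1. Oas1a lost its call without TMut replicate 2 (adjusted p = 0.0527).

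Of 18 measured antigen presentation genes, 9 rose and 0 fell (median 1.05, camera adjusted p = 0.000417, adjusted p = 0.389 with an estimated correlation). B2m (1.10 ± 0.12) and Psmb10 (1.93 ± 0.24), an immunoproteasome subunit, had the smallest adjusted p values, and adjusted over the list alone 11 rose and 0 fell. Of 26 measured p53 targets, 12 rose and 1 fell (median 0.51, camera adjusted p = 0.0066, adjusted p = 0.5 with an estimated correlation). Bax (1.16 ± 0.14), a regulator of apoptosis, and Mdm2 (0.92 ± 0.15), the ubiquitin ligase of p53, led the list, and adjusted over the list alone 14 rose and 1 fell. Without TFoCa replicate 1 (median 0.31, adjusted p = 0.0577) the list call ended. Rrm2b (-0.67), the member that fell, is named after its values were seen. Rrm2b lost its call without TFoCa replicate 2 (adjusted p = 0.0591) and TMut replicate 2 (adjusted p = 0.0751), and with quantile normalization (adjusted p = 0.0593) and in a fit to these 2 genotypes (adjusted p = 0.0849). Of 69 measured extracellular matrix and adhesion genes, 10 rose and 35 fell (median -0.58, camera adjusted p = 0.00214, adjusted p = 0.505 with an estimated correlation and adjusted p = 0.0524 by fry). Spp1 (3.06 ± 0.24), osteopontin, and L1cam (-2.92 ± 0.32), a neural adhesion molecule, led this list, and adjusted over the list alone 12 rose and 35 fell. Without TFoCa replicate 1 (median -0.49, adjusted p = 0.0826) the list call ended. Of 39 measured axon guidance genes, 7 rose and 21 fell (median -0.91, camera adjusted p = 0.000361, adjusted p = 0.404 with an estimated correlation). Nrp2 (-1.42 ± 0.11) and Ntn4 (-2.38 ± 0.25), a receptor and a netrin, led that list, and adjusted over the list alone 7 rose and 23 fell.

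Of 35 measured neuronal differentiation genes, 1 rose and 29 fell (median -2.65, camera adjusted p = 2.21e-11, adjusted p = 0.358 with an estimated correlation). Ina (-1.74 ± 0.13) and Celf4 (-2.56 ± 0.24) had the smallest adjusted p values, and adjusted over the list alone 1 rose and 29 fell. Of 19 measured GABAergic lineage genes, 1 rose and 15 fell (median -2.48, camera adjusted p = 3.65e-06, adjusted p = 0.389 with an estimated correlation). Slc32a1 (-3.85 ± 0.38), the vesicular transporter of GABA, had the smallest adjusted p, and adjusted over the list alone 1 rose and 15 fell. Of 41 measured synapse and ion channel genes, 1 rose and 27 fell (median -1.57, camera adjusted p = 1.25e-09, adjusted p = 0.358 with an estimated correlation). Gria1 (-2.55 ± 0.24) and Grik2 (-2.78 ± 0.29), glutamate receptor subunits, led this list, and adjusted over the list alone 1 rose and 30 fell. Of 30 measured neural stem cell and radial glia genes, 0 rose and 18 fell (median -1.30, camera adjusted p = 1.56e-06, adjusted p = 0.389 with an estimated correlation). Emx2 (-2.07 ± 0.17) and Fgfr2 (-2.14 ± 0.19), a growth factor receptor, led that list, and adjusted over the list alone 0 rose and 21 fell. Of 53 measured clustered protocadherin genes, 0 rose and 27 fell (median -1.08, camera adjusted p = 1.13e-07, adjusted p = 0.358 with an estimated correlation). Pcdhga2 (-1.71 ± 0.26) and Pcdhb13 (-4.09 ± 0.69) led this group, and adjusted over the list alone 0 rose and 34 fell. Pcdhb13 lay at -2.08 with a pseudocount of 8.

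Of 23 measured astrocyte genes, 2 rose and 11 fell (median -0.71, camera adjusted p = 0.00744, adjusted p = 0.358 with an estimated correlation). Mlc1 (-3.30 ± 0.28) and Slc1a2 (-3.24 ± 0.38) had the smallest adjusted p values, and adjusted over the list alone 2 rose and 11 fell. Of 20 measured oligodendrocyte lineage genes, 2 rose and 10 fell (median -1.02, camera adjusted p = 0.00858, adjusted p = 0.358 with an estimated correlation). Nkx6-2 (-2.78 ± 0.29) and Tmem163 (-3.34 ± 0.36) led the list, and adjusted over the list alone 3 rose and 12 fell. Of 21 measured telencephalic patterning genes, 0 rose and 13 fell (median -0.84, camera adjusted p = 6.42e-05, adjusted p = 0.469 with an estimated correlation). Emx2 (-2.07 ± 0.17) and Otx1 (-3.002 ± 0.29) led this list, and adjusted over the list alone 0 rose and 13 fell. The median was -1.33 without TFoCa replicate 1 and -0.56 without TFoCa replicate 2. Of 23 measured caudal patterning genes, 1 rose and 10 fell (median -0.81, camera adjusted p = 0.0101, adjusted p = 0.358 with an estimated correlation). Barhl2 (-3.64 ± 0.39) and Otx2 (-1.55 ± 0.17) led that list, and adjusted over the list alone 1 rose and 10 fell. Gbx2 (2.96 ± 0.49), the member that rose, is named after its values were seen.

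Of 24 measured Notch pathway genes, 0 rose and 16 fell (median -0.83, camera adjusted p = 1.47e-06, adjusted p = 0.358 with an estimated correlation). Dll3 (-2.46 ± 0.30) and Dtx4 (-1.52 ± 0.19) had the smallest adjusted p values, and adjusted over the list alone 0 rose and 19 fell. Of 38 measured Wnt signalling genes, 2 rose and 16 fell (median -0.53, camera adjusted p = 0.0017, adjusted p = 0.358 with an estimated correlation). Wnt7b (-5.08 ± 0.51) and Lef1 (-1.96 ± 0.22), a transcription factor of the pathway, led the list, and adjusted over the list alone 2 rose and 16 fell. Of 15 measured ependymal and choroid plexus genes, 0 rose and 7 fell (median -0.76, camera adjusted p = 0.0168, adjusted p = 0.358 with an estimated correlation). Otx2 (-1.55 ± 0.17), also on the caudal list, and Sostdc1 (-2.28 ± 0.30) led this list. Adjusted over the list alone 0 rose and 7 fell. Without TMut replicate 1 (median -1.46, adjusted p = 0.0555) the list call ended. The median was -0.46 with quantile normalization and -1.31 without TFoCa replicate 1.

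In the neuronal, GABAergic and synaptic lists the members that rose, named after their values were seen, were Nefh (2.34), Lhx6 (0.87) and Gria3 (0.68). Nefh lost its call without TFoCa replicate 1 (adjusted p = 0.0527) and TMut replicate 2 (1.497, adjusted p = 0.0634), and in a fit to these 2 genotypes (adjusted p = 0.0525). Lhx6 lost its call without WT replicate 2 (adjusted p = 0.0569), WT replicate 3 (adjusted p = 0.0528), TFoCa replicate 2 (adjusted p = 0.0883), TMut replicate 1 (adjusted p = 0.1) and TMut replicate 2 (adjusted p = 0.0791), and in a fit to these 2 genotypes (adjusted p = 0.0898). Gria3 lost its call without TMut replicate 1 (adjusted p = 0.0522) and TMut replicate 2 (adjusted p = 0.0872), and in a fit to these 2 genotypes (adjusted p = 0.0692). Gria3 lay at 0.42 without TFoCa replicate 2. Tet2 was lower in TMut than in TFoCa by 1.07 ± 0.28 log2 units (adjusted p = 0.023) and Tdg by 0.36 ± 0.10 (adjusted p = 0.023). Tet2 lost its call without TMut replicate 1 (adjusted p = 0.0548) and TMut replicate 2 (adjusted p = 0.103), and in a fit to these 2 genotypes (adjusted p = 0.0704). Tet2 lay at -0.57 without TFoCa replicate 1. Tdg lost its call without WT replicate 2 (adjusted p = 0.0514), TFoCa replicate 2 (adjusted p = 0.0586), TMut replicate 1 (adjusted p = 0.0666) and TMut replicate 2 (adjusted p = 0.0919), and in a fit to these 2 genotypes (adjusted p = 0.1). Tet1 (0.46 ± 0.31, adjusted p = 0.27) and Tet3 (-0.46 ± 0.18, adjusted p = 0.08) did not pass the test. Tet1 was called without TMut replicate 1 (1.03, adjusted p = 0.00268). Tet3 was called without TMut replicate 1 (-0.70, adjusted p = 0.0213). Of the 4 genes of the TET and TDG list, 0 rose and 2 fell (median -0.41, camera adjusted p = 0.239, adjusted p = 0.496 with an estimated correlation and adjusted p = 0.0154 by fry, which calls it), and adjusted over the list alone Tet2, Tet3 and Tdg fell. The number of changed genes was 3164 without TMut replicate 2, against 6491 with all libraries, and 3419 in a fit to the libraries of these genotypes alone. Among the 167 called genes that the naming rule takes here, 18 (10.8%) lost their call when some library was left out.

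Both mutant genotypes were compared with the same 3 WT libraries, which alone makes their fold changes resemble each other. Ptgs2 rose by 4.18 ± 0.27 log2 units in TFoCa and 4.65 ± 0.27 in TMut, and Mgp, a matrix protein gene, by 3.80 ± 0.44 and 4.90 ± 0.44. Ifi203, whose reads may be shared with related interferon-inducible genes, rose by 3.99 ± 0.78 and 4.94 ± 0.78. Genes that fell in both included Emx1, a cortical transcription factor (-3.78 ± 0.51 and -4.82 ± 0.51), Hs3st4 (-3.08 ± 0.53 and -5.53 ± 0.53) and Gstm3 (-4.03 ± 0.60 and -2.98 ± 0.60). Ifi203 lost its TFoCa call without TFoCa replicate 2 (adjusted p = 0.0822). Hs3st4 lost its TFoCa call without WT replicate 1 (adjusted p = 0.0585) and WT replicate 2 (adjusted p = 0.0621). In all, 674 genes rose in both and 201 fell in both, where independent lists would share 175.6 and 130.1. Simulated data with no effect in either genotype, in which few genes are called at all, gave means of 0.01 and 0. Neither number holds both the effects and the shared WT libraries, so the excess over them is no measure of a shared effect, and part of it may come from the shared libraries. Of the genes changed in both, 246 and 76 also differed between TMut and TFoCa.

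A further 61 genes changed in opposite directions, 27 higher in TFoCa and 34 higher in TMut. All 61 differed in the direct comparison, where opposite changes add up, so this is no further test. Their number was 11, 5 and 6 without WT replicates 1, 2 and 3, 85 and 127 without TFoCa replicates 1 and 2, 140 and 34 without TMut replicates 1 and 2, and 205 with DESeq2. Pamr1 rose by 2.38 ± 0.45 in TFoCa and fell by 3.02 ± 0.45 in TMut. Dnmt3l fell by 2.74 ± 0.60 and rose by 2.16 ± 0.60, and Tdgf1 fell by 3.27 ± 0.54 and rose by 2.09 ± 0.54. Pamr1 lost its TFoCa call without WT replicate 1 (adjusted p = 0.059), WT replicate 2 (adjusted p = 0.0502), WT replicate 3 (adjusted p = 0.0605) and TFoCa replicate 1 (adjusted p = 0.0728). Dnmt3l lost its TFoCa call without WT replicate 1 (adjusted p = 0.0508), WT replicate 2 (adjusted p = 0.0959), WT replicate 3 (adjusted p = 0.0938), TFoCa replicate 1 (adjusted p = 0.0891) and TFoCa replicate 2 (adjusted p = 0.0716), and with voom (adjusted p = 0.226). Tdgf1 lost its TFoCa call without WT replicate 2 (adjusted p = 0.0518), and with voom (adjusted p = 0.156). Dnmt3l and Tdgf1 lost their TMut calls without WT replicates 1 and 3 and TMut replicate 2 (1.14 and 1.05), as given above. Of the 654 genes called in TFoCa alone, 520 (79.5%) differed between TMut and TFoCa, as did 4248 (69.6%) of the 6107 called in TMut alone. Choosing genes by their calls on the same libraries shapes these shares. Across genes, which are not independent replicates, the correlation of the fold changes was 0.3183, against a mean of 0.4007 in the simulations without effect. The covariance was 0.3096, against 0.05882. The number of genes changed in the same direction was 464, 330 and 384 without WT replicates 1, 2 and 3, against 875 with all libraries.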

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

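The test of the mesenchymal genes, the trends without mean level and the thinning were chosen after the data were seen; the other tests were written before their results were seen. All 8 gene lists given here had medians of opposite sign in TFoCa and TMut against WT, a call in at least 1 of them, and a direct test of TMut against TFoCa that passed. None of these calls held with an estimated inter-gene correlation. For 5 lists the median that was not called turned its sign with 1 library left out, so their opposite signs rest on single lines. Without TFoCa replicates 1 and 2 in turn, the TFoCa median was -0.04 and 0.466 (called, adjusted p = 0.00809) for synapse and ion channels, -0.009 and 0.127 for protocadherins, 0.097 and -0.038 for the Notch pathway, and 0.141 (called, adjusted p = 0.00202) and -0.195 (called, adjusted p = 8.39e-06) for ribosomal proteins. Without TMut replicates 1 and 2 in turn, the TMut median for pluripotency was 1.021 (called, adjusted p = 0.000509) and -0.218, and without WT replicate 2 it was 0.479 (called, adjusted p = 0.0496).

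The median log2 difference of TMut from TFoCa was 4.188 for the pluripotency list, from -3.526 in TFoCa and 0.319 in TMut against WT. Thinning all libraries to the same total left the TFoCa median at -3.458 (bootstrap interval -4.345 to -2.735), which argues against sequencing depth. The intervals of list medians given here and below come from resampling the genes of a list, not the libraries. They do not measure the spread between lines. A second list of 16 markers of pluripotent cells, written before its values were seen, had a median of -2.731 (-3.411 to -1.8) in TFoCa, with 10 members lower (camera p = 3.31e-10 with the preset correlation, p = 0.124 with an estimated correlation, both unadjusted; 8, 5 and 6 lower without WT replicates 1, 2 and 3). This is consistent with fewer residual pluripotent cells in the TFoCa lines, as a hypothesis. Lower expression per cell would give the same values in bulk RNA, and the pluripotency genes also varied between lines of 1 genotype, with a median log2 ratio of 1.499 between TMut replicates 2 and 1.

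Neural lists were lower in TMut, and the difference of TMut from TFoCa was -1.574 for synapse and ion channel genes (0.215 in TFoCa, -1.585 in TMut), -0.833 for the Notch pathway (0.058, -0.846) and -1.08 for clustered protocadherins (0.123, -0.946). Quantile normalization left the neuronal median at -2.709 (-3.394 to -2.445). It moved that of all genes only from 0.002 to 0.058, so it tests scaling weakly. A lower share of neural cells would raise markers of other cells alike, but 18.18% of the 22 called mesenchymal members were lower in TMut (4 of 22, exact binomial p = 0.0222 against 5%). Without TMut replicate 2 the 4 calls were lost, with Fbln2 at -1.383, Col5a2 at -1.219, Pdgfrb at -0.492 and Col1a1 at -0.275. Genes of a list are not independent and these calls rest on 1 line, so the test does not decide. A lower neural share, with other cells changed or not, and an effect of the genotype stay open.

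Ribosomal protein genes differed by 0.445 between TMut and TFoCa (0.269 without TFoCa replicate 1 and 0.199 with quantile normalization; -0.032 in TFoCa, 0.392 in TMut), and oxidative phosphorylation genes by 0.584 (-0.154, 0.419), beside a higher share of mitochondrial reads in TMut (1.053% and 1.111%, against 0.7805% to 0.9253% elsewhere). TMM factors gave a ribosomal median of 0.426 in TMut (0.39 to 0.47). They moved that of all genes only from 0.002 to 0.036, a weak test of a scale factor. Quantile normalization, which also removes shifts that follow level, gave 0.135. Removing the trend with transcript length, GC content and mean level brought the ribosomal median to 0.017 (-0.044 to 0.064), which met the criterion written for length and GC bias, and the oxidative phosphorylation median to 0.127 (-0.027 to 0.203), which decides nothing. With mean level left out of the trend the medians stayed at 0.332 (0.292 to 0.387) and 0.399 (0.201 to 0.441), so length and GC alone do not account for either. A shift that follows expression level, technical or biological, may account for the ribosomal values, and the tests here do not separate these.

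The germline list differed by 2.445 between TMut and TFoCa (1.417 without TMut replicate 2; -1.654 in TFoCa, or -0.806 without TFoCa replicate 1 and -0.957 with a pseudocount of 8, and 0.845 in TMut, or 1.947 (called, adjusted p = 0.00098) without TMut replicate 1 and 0.108 without TMut replicate 2). In TMut it was also called without WT replicate 2 (1.046, adjusted p = 0.00992), and without TFoCa replicates 1 and 2 (adjusted p = 0.0455 and 0.0467). The axon guidance list differed by -0.907 (0.541 in TFoCa, or 0.288 without TFoCa replicate 1, and -0.313 in TMut, or -0.547 without TMut replicate 1).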

How the results depend on the processing

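Called gene numbers in TFoCa versus WT moved from 1590 to 2947 with DESeq2, 555 with a replicate block, 810 with a log2 change of 1 or more and 2907 at an adjusted p under 0.1, and ranged from 495 to 1768 when 1 library was left out. In TMut versus WT they moved from 7043 to 4620 with the block and 3572 with a log2 change of 1 or more, and ranged from 4329 to 8127. In TMut versus TFoCa they moved from 6491 to 3419 with 2 genotypes only and 3250 with a log2 change of 1 or more, and ranged from 3164 to 5940. The overlap moved from 875 to 1511 with DESeq2 and 329 with the block, and ranged from 330 to 1047; genes in opposite directions moved from 61 to 205 and 9, and ranged from 5 to 140. Called lists fell to 0 in each comparison with an estimated correlation and otherwise ranged from 17 to 20, 21 to 23 and 24 to 25 when 1 library was left out. A required log2 change can only lower these numbers and the threshold of 0.1 only raise them. The block in effect leaves out WT replicate 3, the only library so numbered. The cause of other shifts was not tested. Thinning, added after the data were seen, gave 1556, 6961 and 6405 genes. Replicate numbers were not taken to pair the libraries, so the block is an alternative only. Over every called gene that the naming rule takes, 96 of 465 (20.6%) lost their call when some library was left out and 5 more were then below the filter, with 54 of 127 in TFoCa versus WT; among list calls, 16 of 65 did. The ribosomal list in TFoCa versus WT, not called, was called at 0.141 (adjusted p = 0.00202) without TFoCa replicate 1 and at -0.195 (adjusted p = 8.39e-06) without TFoCa replicate 2. Y-linked genes, not called, differ between the TFoCa lines and were called in opposite directions with the library left out. Without TFoCa replicate 1 and 2 in turn, Ddx3y lay at 3.456 and -1.585 and Eif2s3y at 2.719 and -2.889 in TFoCa versus WT; in TMut versus TFoCa, Ddx3y lay at -2.72 and 2.32, Kdm5d at -3.162 and 3.049 and Uty at -1.664 and 2.495. A lone remaining library was assumed to vary like the other groups. Over the genes and lists named, 4461 gene and 1368 list results under alternatives stayed on the same side of the threshold (15 and 46 of these, called in neither setting, turned the sign of their value), 194 and 110 lost their call (21 and 2 of these with the block), and 55 and 42 gained one. Depth limits genes with few reads, which the table omits.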

Other observations

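TFoCa lines had more RNA of skeletal muscle genes than WT lines. Myod1 (2.81, adjusted p = 0.0102) and Myog (2.704, adjusted p = 0.01), transcription factors of muscle, Chrng (2.96, adjusted p = 0.00942) and Des (2.26, adjusted p = 0.0374) rose in log2 units by limma and are named after their values were seen. Des lost its call without WT replicates 1, 2 and 3 (adjusted p = 0.102, 0.115 and 0.0957), and with robust eBayes and voom (adjusted p = 0.051 and 0.0634). It lay at 1.246 without TFoCa replicate 2. The hypothesis that muscle genes rise as a group was then tested on a list that leaves these 4 out, written before its values were seen. Of its 23 measured members 13 rose and 0 fell, with a median of 1.732 and all 23 above 0 (camera p = 3.09e-14 with the preset correlation, p = 0.0811 with an estimated correlation, both unadjusted). The size depends on the line: all 23 were higher in TFoCa replicate 2 than in replicate 1. The median was 1.103 without TFoCa replicate 2 and 2.452 without replicate 1. Acta1 and Myh3, named after their values were seen, had 645.6 and 2477 normalized counts in TFoCa replicate 1 and 3007.5 and 10660.9 in replicate 2. WT libraries had 353.7 to 723.3 and 677.6 to 1205, and TMut libraries 1078.1 to 1179.5 and 1004.9 to 1763.4, so no line lacked their RNA. Without WT replicates 1, 2 and 3, 6, 3 and 5 members were called. More muscle-like expression in part of the TFoCa cells than in WT is a hypothesis that the estimated correlation leaves open. In TMut versus TFoCa, 10 of the 23 were lower and 0 higher (median -1.388). The median was -0.895 and -2.033 without TFoCa replicates 2 and 1, and -1.012 without TMut replicate 2.

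Imprinted genes went both ways in TMut against WT, with 10 of 52 higher and 15 lower (median -0.05, camera adjusted p = 0.672, adjusted p = 0.899 with an estimated correlation); adjusted over the list alone 10 were higher and 16 lower. With 1 library left out the median lay between -0.168 and 0.01. Igf2r rose by 1.78 ± 0.12 and Blcap fell by 0.85 ± 0.09 log2 units. Of 29 genes of the ATF4 and unfolded protein response list, 12 rose and 2 fell in TMut, also adjusted over the list alone (camera adjusted p = 0.3, adjusted p = 0.629 with an estimated correlation). Manf (1.02 ± 0.12) and Creld2 (0.96 ± 0.14) led the list; its median (-0.53, from -0.967 to -0.085 with 1 library left out) and the direction of its test (higher) differ in sign.

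Y-linked genes had reads in all 7 libraries but differed between lines. Kdm5d had 1492.2 normalized counts in TFoCa replicate 2, 278.7 and 98.4 in TMut replicates 1 and 2, and 18.4 to 22 in the other libraries. Ddx3y had 3152.4 in TFoCa replicate 2, 94.8 in TFoCa replicate 1 and 231.2 to 573.6 elsewhere. In TMut versus WT, Eif2s3y (1.866), Kdm5d (2.978) and Uty (1.532) were not called over all libraries, but were in a fit to these 2 genotypes (adjusted p = 0.00135, 0.00312 and 0.0036) and without TFoCa replicate 1 (adjusted p = 0.00127, 0.00241 and 0.00316) or 2 (adjusted p = 0.00148, 0.00333 and 0.00385). Xist had 2.4 to 25.2 in all libraries. It was higher in TMut than in TFoCa by 2.62 ± 0.55 log2 units (adjusted p = 0.01), a call lost without TMut replicate 2 (adjusted p = 0.0512) and in a fit to these 2 genotypes (adjusted p = 0.0507), and by 1.531 with a pseudocount of 8. In TMut versus WT it was not called (1.244, adjusted p = 0.0857), but was with a pseudocount of 8 (0.861, adjusted p = 0.0476) and with voom (adjusted p = 0.0497). Against the WT mean, library medians of 488 X-linked minus autosomal genes were -0.145 to 0.048 log2 units.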
